A study of Mus musculus with 14 samples.

How the data were processed

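RNA sequencing of mouse gastric organoids was deposited as 3 count tables and 3 tables of normalised values, with 14 libraries in 6 groups. The bulk table holds 2 TP and 2 TPA libraries from populations, that of the clones 2 TP and 2 TPA clones, and the treatment table has 3 TPA libraries with DMSO and 3 with 10 µM dBRD9. The processing notes of the authors give STAR 2.6.0 on mm10 for alignment and DESeq2 1.22.2 for normalisation, with no DESeq2 version for the clones. The counting tool, its annotation and its filters are not given in the sources used here. The deposited counts are whole numbers per gene symbol, not normalised. The deposited signal in the normalised tables is those counts divided by 1 factor per library, with a ratio spread of at most 1.2e-09 within a library. That this factor is DESeq2's size factor rests on the processing notes. The bulk and treatment tables list 24421 symbols each, 5897 and 6885 of them with 0 counts throughout, and the clone table lists 17642, none of them 0 throughout. Symbols that a spreadsheet had turned into dates numbered 27, 24 and 27 and held 0.164%, 0.171% and 0.171% of the counts. They stayed in each table's own test and were left out of every join between tables.

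Columns were matched to groups by name. The bulk columns are numbered 1 and 2, while the bulk TPA labels run 2 and 3, so a bulk column gives its group but not its replicate, and the TPA replicate 1 that these labels imply is not analysed here. The bulk labels share number 2 alone, so they pair no columns, and a block on column number was an alternative. Clone numbers name separate lines, and a block on them was an alternative too. In the treatment table the labels do not say that a number marks a shared culture or day. Same-number libraries there did not resemble each other once group means were taken out (correlations of -0.202, -0.0105 and -0.0145), so a block on replicate number was an alternative only. Every column of per-sample values was used.

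Counts were analysed in R 4.3.3 with edgeR 4.0.16, each table alone. Genes were kept by filterByExpr with the groups, libraries were scaled by TMM, and the quasi-likelihood test was run per comparison. Benjamini-Hochberg adjustment ran over the genes tested, with calls at an adjusted p under 0.05. The difference between the clone and bulk effects was tested the same way on 17618 symbols joined over the 8 libraries. Levels are TMM-scaled CPM. Log2 CPM used a prior count of 2. The upper limit for a count of 0 is 3 counts over the library total, and covers counting error only, since reads without molecular identifiers are not independent molecules.

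Before the data were examined, 26 lists with 439 members in all were fixed, along with the comparisons, tests, naming rule and most alternatives. The lists are mucins, pit, neck and gland, chief, parietal, endocrine, tuft, intestinal, squamous forestomach, stromal with endothelial and immune markers, WNT targets, mucin O-glycosylation, secretory granule exocytosis, ER stress, gastric transcription factors, cell cycle, p53 targets, SWI/SNF, interferon, NF-kB, cholesterol synthesis, mesenchymal, immediate early, hypoxia, MYC and xenobiotic metabolism. Each list with at least 3 tested members was tested by camera (limma 3.58.1) against all other genes with a preset correlation of 0.01, giving 74 list tests over 3 comparisons, adjusted within each comparison. An estimated correlation and fry were alternatives. fry asks whether a list's genes move on balance 1 way, and its mixed form whether they change either way, and neither compares a list with other genes. Overlaps were tested by Fisher's exact test, two-sided, among genes tested in both, with the number that independent lists would share beside each count.

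Genes were named by rule. Arid1a, Pten, Trp53 and Brd9 were named in every comparison. Each comparison also gave the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 CPM and groups wholly apart, without symbols that begin with Gm and a digit, end in Rik or hold -ps. Each list gave up to 4 members with the smallest p, and Muc1, Muc5ac, Muc6, Muc13, Capn9 and Tff1 were always followed. Each overlap gave up to 10 genes by the smallest larger p. Named from list membership or level after the values were seen were Trp63 with dBRD9 and Dsg3 with dBRD9, Cyp1b1 with dBRD9, and in the closing part Krt5, Krt8, Krt18, Eif2s3y, Ddx3y, Eml1, Ptprc and Col1a1 in bulk.

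Depth was 12864217 to 27271964 counts per library, and the 10 most abundant genes took 4.42% to 7.25% of it. Replicates correlated at 0.966 and 0.971 in bulk, 0.997 and 0.968 in the clones and 0.997 to 0.998 in the treatment table, as Pearson r of log2 CPM across genes, which are not independent replicates. The common biological coefficient of variation was 0.487 in bulk, 0.313 in clones and 0.0915 in the treatment table. The tests were tested on simulated data with 200 changed genes at each comparison's own spread. The edgeR test recovered 0% of 2-fold and 0% of 4-fold changes in bulk, 4% and 57% in clones, and 81% and 96% in the treatment table, where 13 of 190 calls were false. DESeq2 recovered 4% and 42% in bulk, with 58 of 104 calls false, and 25% and 79% in clones, with 48 of 152 calls false. For the difference between clone and bulk effects edgeR recovered 0% at either fold, against 67% and 89% with a dispersion of 0.01.

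Alternatives were relative log expression and total counts as scaling, DESeq2 1.42.0 and limma-voom as tests, no low-count filter, a mean of at least 5 CPM, the deposited normalised values, all 6 groups in 1 fit, a replicate block, a fold change of at least 2, and leaving out each library in turn. After the data were seen, 11 alternatives were added. The block on column number was added for the bulk calls and for the bulk list tests. For the calls and list tests of each comparison, each library's trends of log2 CPM on exonic length and GC were removed by splines with 5 degrees of freedom. Both kinds of overlap were also taken at an unadjusted p under 0.05 in the guide comparisons, and those with dBRD9 also with the trends removed. Length, GC and position came from GENCODE vM21 on GRCm38, in which 96.2% of the tested symbols of each table were found. On simulated data with a length trend, the correction took false calls from 1516 to 12. It recovered 92% of the changed genes with an annotation, against 89.5% of all changed genes before it. The changed genes were drawn at random, so this cannot show how the correction treats a real effect that follows length.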

Results

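RNA was sequenced from mouse gastric organoids in which CRISPR guides had been put into Trp53-/- organoids that carry Cas9. TP organoids carry guides against Pten, and TPA organoids carry guides against Pten and Arid1a. Arid1a encodes a DNA-binding subunit of the canonical BAF form of SWI/SNF, the ATP-dependent chromatin remodeler, and Pten encodes the phosphatase that restrains PI3K signalling. The series asks what ARID1A does in the making and release of mucin, with gastric signet ring cell carcinoma in view. The 14 libraries fall into 6 groups, in 3 count tables. Populations without clonal isolation gave 2 TP and 2 TPA libraries, here called bulk, and single-clone lines gave 2 TP clones and 2 TPA clones. TPA organoids treated with DMSO, the solvent, gave 3 libraries, and those treated with dBRD9 gave 3. dBRD9 is a degrader of BRD9, a subunit of the non-canonical BAF form of SWI/SNF, and was added at 10 µM after 24 h of culture. The labels call the bulk TP organoids premalignant and the bulk TPA organoids tumor, so that difference goes with the guide. They give total RNA for the bulk and treatment libraries and polyA RNA for the clones. Clone labels name separate lines, but no label says that the other replicates are separate cultures or animals. Each p thus measures only the spread between these libraries, which in the treatment libraries may be technical. That spread was unequal, with a chi-square of replicate counts per degree of freedom of 180.5 in bulk TP and 106.8 in bulk TPA. It was 9.19 in the TP clones, 174 in the TPA clones and 6.9 to 17.45 in the treatment libraries. The bulk values argue against mere technical repeats there, where Krt5 for example stood at 692 and 7370 CPM in bulk TP. The TP clones were as alike as the treatment libraries, though labelled as separate lines.

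Library totals were 12864217 and 17963270 counts in bulk TP and 16457350 and 16479292 counts in bulk TPA. The TP clones had 23187277 and 25289483 counts and the TPA clones 27271964 and 23206160. The dBRD9 libraries held 20510367, 18002075 and 18304545 counts, and the DMSO libraries 16650296, 23246289 and 16684146. A gene with 0 counts in a library could have been present at up to 0.11 to 0.233 CPM, the usual unit of counts scaled to library size, as far as counting error goes. Levels below are means of TMM-scaled CPM with the SD between libraries. A library's own level is its CPM over its own total.

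The bulk comparison asks how populations with the Arid1a guide differ from those without it. Arid1a itself (chromosome 4, 133679008 to 133756769, minus strand, on GRCm38 like every position here) stood at 200.7 ± 49.7 CPM in TP and 144 ± 35.9 CPM in TPA (SD, n = 2), a log2 fold change of -0.48 ± 0.34 (SE). Several mucin transcripts had a higher mean in TPA. Muc1, a transmembrane mucin (chromosome 3, 89229057 to 89233381, plus strand), averaged 59.7 ± 78.3 CPM in TP and 615 ± 74.5 CPM in TPA (SD, n = 2). Muc4, another transmembrane mucin (chromosome 16, 32735886 to 32782391, plus strand), averaged 89.3 ± 87.5 against 690 ± 183 CPM, and both TPA libraries lay above both TP libraries for each of these genes. None of these genes passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, with adjusted p of 0.763 for Arid1a, 0.673 for Muc1 and 0.558 for Muc4. Muc4 passed by DESeq2 (adjusted p = 0.00613) and by edgeR's test with all 6 groups in 1 fit (adjusted p = 0.0379). The latter fit shares 1 dispersion per gene with the less variable clone and treatment libraries, which tends to understate the bulk spread. On simulated bulk data 58 of 104 DESeq2 calls were false. That share depends on how many genes truly change, which the simulation fixed, so it gives no false share for the real calls.

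The gel-forming and membrane mucins were higher in TPA as a list, with 6 of 8 tested members positive and a median log2 fold change of 2.41 (camera adjusted p = 0.00106). With an estimated correlation the adjusted p was 0.791. Muc5ac, the gel-forming mucin of the gastric surface (chromosome 7, 141788972 to 141819231, plus strand), averaged 18.6 ± 25.7 CPM in TP and 199 ± 190 CPM in TPA (SD, n = 2). The membrane mucin Muc20 averaged 1.26 ± 0.361 and 11.8 ± 6.83 CPM (adjusted p = 0.00341 by DESeq2), and the gland mucin Muc6 3.23 ± 3.06 and 2.9 ± 1.96 CPM. Muc13 was too low to test, with 4 counts in TP and 135 in TPA, as was Capn9, a calpain of gastric mucous cells, with 0 and 4. The TP libraries differed widely here, since Muc1 stood at 118 CPM in column 1 and 4.29 CPM in column 2. The mucin list averaged 4.67 and 1.14 log2 CPM in the TP columns and 4.79 and 5.98 in the TPA columns, so TP column 1 lay close to TPA column 1. Without TP column 2 the mucin list had an adjusted p of 0.284. Markers of pit cells, the surface mucous cells of the stomach, were positive in 9 of 9 tested members (median 2.61, adjusted p = 0.00135, and adjusted p = 0.794 with an estimated correlation). Examples were Vsig1, an adhesion protein, at 1.55 ± 2.11 and 28.4 ± 12.6 CPM, and Psca, a surface protein, at 101 ± 58 and 264 ± 76.8 CPM. Tff1, the pit cell trefoil factor, stood at 0.418 ± 0.591 and 1.74 ± 2.11 CPM. The pit list averaged 4.74 and -1.12 log2 CPM in the TP columns and 2.43 and 7.12 in the TPA columns. Its adjusted p was 0.284 without TP column 2 and 0.596 without TPA column 2.

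Interferon response genes were higher in bulk TPA in 26 of 26 tested members, with a median log2 fold change of 1.94 (adjusted p = 3.61e-16, and adjusted p = 0.791 with an estimated correlation). Oasl1, an interferon-induced antiviral gene, stood at 18.2 ± 15.7 CPM in TP and 277 ± 81.2 CPM in TPA (SD, n = 2). Zbp1, a sensor of Z-form nucleic acid, averaged 3.82 ± 3.47 and 74.4 ± 51.2 CPM, and the interferon-induced GTPase Gbp2 3.68 ± 1.77 and 30.3 ± 15.8 CPM. The list's mean level was 3.48 and 5.80 log2 CPM in the TP columns and 7.70 and 6.23 in the TPA columns. Xenobiotic and glutathione metabolism was higher in 17 of 19 tested members (mean 1.57, adjusted p = 7.89e-08, and adjusted p = 0.791 with an estimated correlation). Cyp1b1, a cytochrome P450, stood at 0.568 ± 0.486 and 44.9 ± 5.47 CPM (log2 fold change 6.33 ± 0.75 SE). Nqo1, a quinone reductase, averaged 45.8 ± 0.675 and 373 ± 328 CPM, and Hmox1, haem oxygenase 1, 10.3 ± 2.39 and 47.3 ± 15.2 CPM. Without TPA column 2 this list had an adjusted p of 0.143.

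Squamous forestomach markers were lower in bulk TPA in 11 of 13 tested members (median -0.80, adjusted p = 2.72e-04, and adjusted p = 0.791 with an estimated correlation). Dsg3, a desmosomal cadherin of squamous epithelium, averaged 136 ± 15.5 CPM in TP and 42.5 ± 8.72 CPM in TPA (SD, n = 2). Ivl, a cornified envelope protein, stood at 58.2 ± 42.9 and 11 ± 5.04 CPM, and Trp63, the p63 transcription factor of squamous epithelium, at 377 ± 221 and 152 ± 12.6 CPM. ER stress and protein folding was lower in 16 of 20 members (median -0.29, adjusted p = 0.00722, and adjusted p = 0.81 with an estimated correlation). Agr2, a disulfide isomerase of mucous cells, averaged 222 ± 174 and 15.5 ± 5.86 CPM, and Ern1, the IRE1 sensor of unfolded protein, 229 ± 112 and 67.9 ± 6 CPM. The ER list had an adjusted p of 0.106 without TP column 1 and 0.238 without TPA column 2.

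Markers of stromal, endothelial and immune cells were higher in bulk TPA in 8 of 8 tested members (median 3.01, adjusted p = 0.00106, and adjusted p = 0.791 with an estimated correlation), alongside the mucin, pit and interferon lists. Dcn, a matrix proteoglycan, stood at 0.464 ± 0.418 CPM in TP and 78.9 ± 111 CPM in TPA (SD, n = 2), and Cd14, a lipopolysaccharide co-receptor, at 120 ± 86.7 and 553 ± 80 CPM. This list averaged 2.64 and -0.29 log2 CPM in the TP columns and 1.76 and 5.57 in the TPA columns, and its adjusted p was 0.347 without TPA column 2. Mesenchymal genes were higher in 10 of 13 tested members (median 0.67, adjusted p = 0.0357, and adjusted p = 0.794 with an estimated correlation). Itga5, the fibronectin receptor subunit, averaged 8.29 ± 2.68 and 52.4 ± 32.6 CPM, and Sparc, a matrix protein, 0.67 ± 0.234 and 44.9 ± 62.6 CPM. The mesenchymal adjusted p was 0.284 without TP column 2 and 0.952, with the direction turned, without TPA column 2.

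Of 13299 genes tested in bulk, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 in either direction, with a lowest adjusted p of 0.351. At an unadjusted p under 0.05 it had 725 higher and 316 lower, 7.83% of the genes. DESeq2 called 357 higher and 87 lower, and limma-voom called 0. Pten, Trp53 and Brd9 had log2 fold changes of -0.02, 0.09 and 0.27, with adjusted p of 0.989, 0.963 and 0.896. Adjusted over the list alone, 2 xenobiotic genes and 2 tuft cell markers were higher, 1 squamous and 1 parietal marker were lower, 1 NF-kB gene was higher, and the intestinal list had 1 higher and 1 lower. The intestinal members were Fcgbp, a secreted goblet cell protein at 0.658 ± 0.179 against 24.6 ± 13.5 CPM, and Spink4, a goblet cell peptide at 42.3 ± 9.95 against 3.3 ± 1.85 CPM (SD, n = 2). Over all genes tested 0 members of any list were called, and the other lists, mucins, pit and interferon included, had 0 adjusted over the list alone. The lists that passed no camera test were secretory granule exocytosis (adjusted p = 0.0767), tuft (0.19), WNT (0.277), neck and gland (0.317), SWI/SNF (0.364) and immediate early genes (0.465). So were chief, parietal, endocrine, O-glycosylation and cell cycle (each 0.754), NF-kB (0.859), gastric transcription factors (0.89), intestinal and cholesterol (each 0.922), and p53, hypoxia and MYC (each 1.0). Median, mean and camera direction differed in sign for the intestinal, gastric transcription factor, cholesterol, immediate early, hypoxia and MYC lists.

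**Figure D1:**
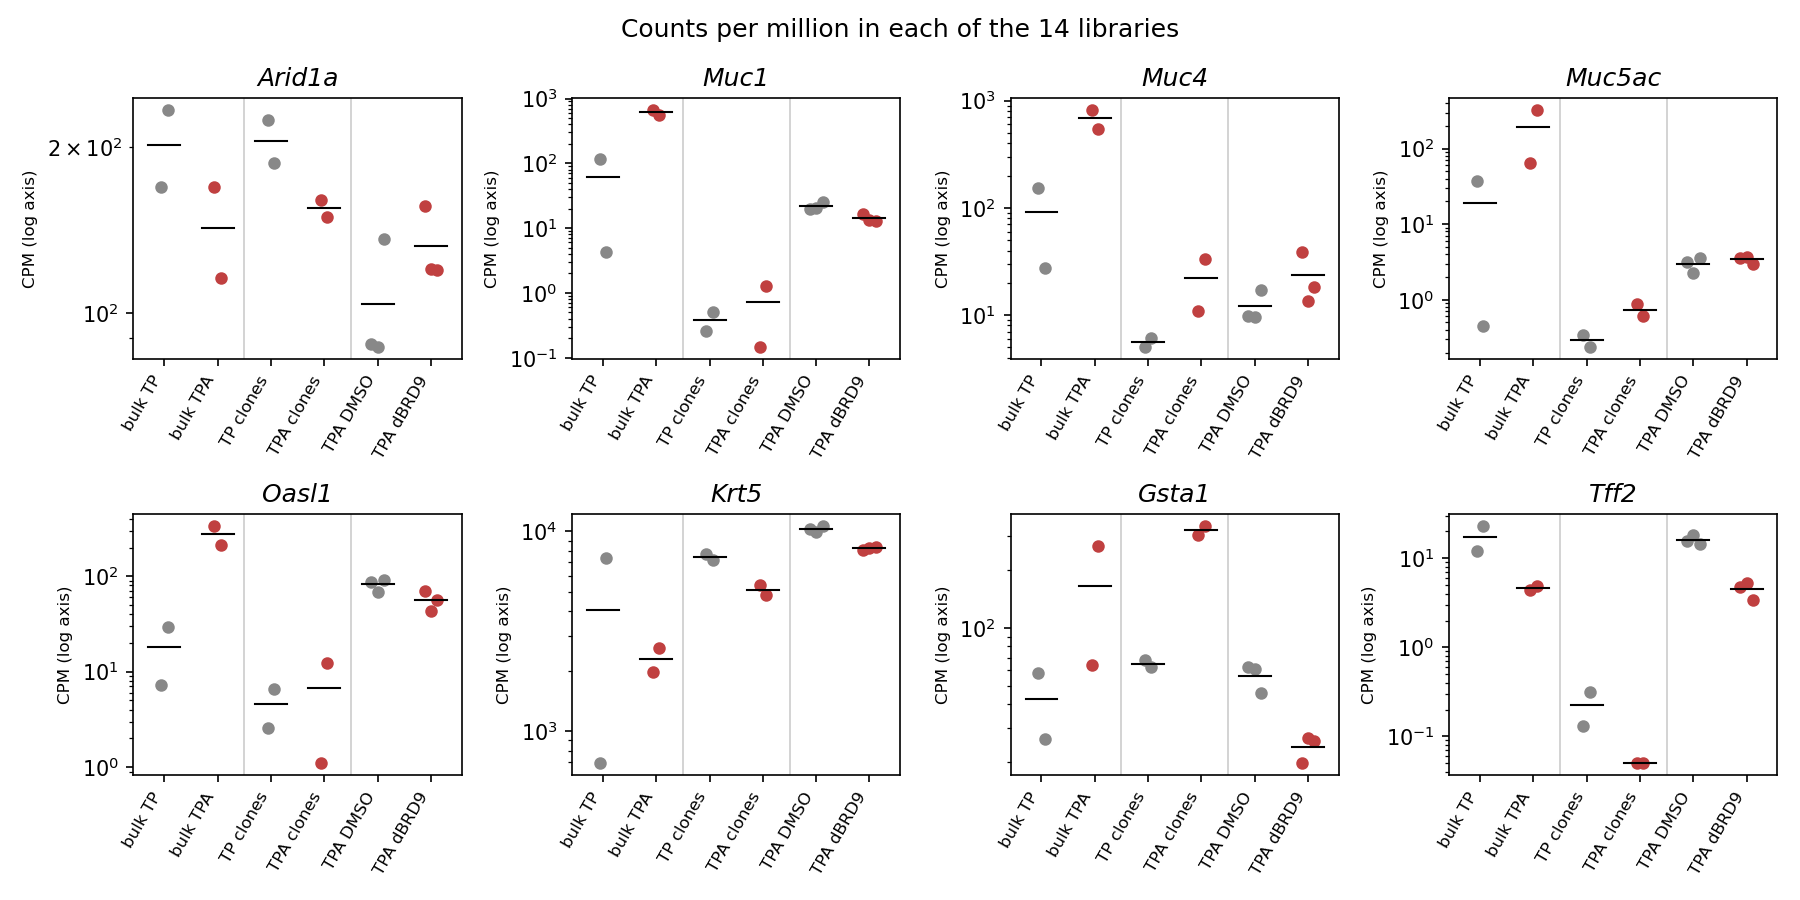
Level of 8 genes (Arid1a, Muc1, Muc4, Muc5ac, Oasl1, Krt5, Gsta1 and Tff2) in each of the 14 libraries, in CPM on a log axis. Each point is a library, grey for TP or DMSO and red for TPA or dBRD9, bars are group means, and values at or near 0 are drawn at 0.05. Muc1 stood at 118 and 4.29 CPM in the bulk TP libraries and at 669 and 549 CPM in the bulk TPA libraries.

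The same guide was compared in lines each grown from an isolated clone. Arid1a stood at 208 ± 23 CPM in TP clones and 153 ± 9.05 CPM in TPA clones (SD, n = 2), a log2 fold change of -0.45 ± 0.16 (SE). Gsta1, a glutathione S-transferase, averaged 66 ± 3.06 and 317 ± 21.2 CPM, and Ankrd37, a hypoxia-responsive gene, 9.64 ± 0.315 and 46.1 ± 2.02 CPM. Rnf43, the ubiquitin ligase that removes WNT receptors, averaged 63.8 ± 4.05 and 22.2 ± 3.34 CPM. Among the mucins, Muc1 stood at 0.394 ± 0.19 and 0.707 ± 0.794 CPM, Muc5ac at 0.295 ± 0.0722 and 0.733 ± 0.199 CPM, and Muc4 at 5.65 ± 0.846 and 21.8 ± 15.5 CPM. By edgeR's quasi-likelihood test the adjusted p was 0.254 for Arid1a, 0.15 for Gsta1 and Ankrd37, and 0.156 for Rnf43. With no low-count filter it was 0.0319 for Gsta1 and 0.0351 for Ankrd37, and by DESeq2 1.09e-16, 7.16e-12 and 1.85e-05 for Gsta1, Ankrd37 and Rnf43.

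Xenobiotic and glutathione metabolism was higher in TPA clones in 16 of 18 tested members (median 0.76, camera adjusted p = 9.64e-04, and adjusted p = 0.565 with an estimated correlation). Adjusted over the list alone, 7 members were higher and 1 lower. Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, averaged 464 ± 0.256 and 1139 ± 354 CPM (SD, n = 2), and Aldh3a1, an aldehyde dehydrogenase, 484 ± 16.4 and 958 ± 81.5 CPM. Hypoxia and glycolysis was higher in 10 of 14 members, with 3 higher adjusted over the list alone (median 0.31, adjusted p = 0.0272, and adjusted p = 0.565 with an estimated correlation). Vegfa, the endothelial growth factor, averaged 218 ± 10.9 and 518 ± 110 CPM, and Egln3, a prolyl hydroxylase of HIF proteins, 452 ± 22.4 and 1051 ± 146 CPM. The hypoxia list's adjusted p was 0.116 without TP clone 1 and 0.297 without TPA clone 2.

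WNT target and stem cell genes were lower in 11 of 14 members, with 5 lower and 2 higher adjusted over the list alone (median -0.70, adjusted p = 0.0142, and adjusted p = 0.565 with an estimated correlation). Axin2, a feedback inhibitor of WNT signalling, averaged 27 ± 3.77 CPM in TP clones and 7.69 ± 1.56 CPM in TPA clones (SD, n = 2), and Znrf3, a partner of Rnf43, 75.3 ± 5.92 and 35.2 ± 3.19 CPM. This list's adjusted p was 0.083 without TPA clone 1, 0.222 without TPA clone 2 and 0.0515 with trends on gene length and GC removed. Cholesterol synthesis was lower in 15 of 18 members, with 3 lower adjusted over the list alone (median -0.39, adjusted p = 0.00195, and adjusted p = 0.565 with an estimated correlation). Fdps, farnesyl diphosphate synthase, averaged 155 ± 6.98 and 70.1 ± 2.74 CPM, and Lss, lanosterol synthase, 165 ± 11.1 and 75.7 ± 20.3 CPM. Without TPA clone 2 its adjusted p was 0.314. SWI/SNF subunits, a list that holds Arid1a, were lower in 22 of 26 members, 0 of them called adjusted over the list alone (median -0.36, adjusted p = 0.00161, and adjusted p = 0.565 with an estimated correlation). Smarca4, the BRG1 ATPase, averaged 263 ± 3.01 and 172 ± 6.4 CPM, and Gltscr1, a subunit of non-canonical BAF, 33.5 ± 4.05 and 17.8 ± 1.35 CPM.

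Mucin O-glycosylation enzymes were higher in TPA clones in 16 of 22 members, with 1 higher adjusted over the list alone (median 0.39, adjusted p = 0.0184, and adjusted p = 0.565 with an estimated correlation). That member was Gcnt1, which branches core 1 glycans, at 22.7 ± 4.27 and 80.8 ± 10.5 CPM (SD, n = 2), and the sialyltransferase St3gal1 stood at 52.2 ± 2.59 and 96.2 ± 15.2 CPM. The O-glycosylation adjusted p was 0.0602 without TP clone 1 and 0.0515 with trends on gene length and GC removed. NF-kB and epithelial inflammation was higher in 16 of 17 members, with 1 higher adjusted over the list alone (median 0.66, adjusted p = 0.00689, and adjusted p = 0.565 with an estimated correlation). Tnfaip3, a feedback inhibitor of NF-kB, averaged 24 ± 3.15 and 51.4 ± 1.2 CPM, and the cytokine Il1a 1.09 ± 0.0706 and 47.9 ± 51.3 CPM. Stromal, endothelial and immune markers were positive in 4 of 4 tested members, with 1 higher adjusted over the list alone (median 2.81, adjusted p = 0.00689, and adjusted p = 0.565 with an estimated correlation). That member was Cd68, a lysosomal protein of macrophages, at 13.4 ± 1.21 and 71.6 ± 30.3 CPM, while the collagen Col1a1 stood at 0.272 ± 0.0176 and 2.57 ± 2.71 CPM. With clone numbers as a block, though they pair no lines, edgeR's test gave Gcnt1, Il1a and Cd68 adjusted p of 0.0414, 0.0288 and 0.03. Squamous markers did not pass (adjusted p = 0.0962), with 4 higher adjusted over the list alone, such as Dsg3 at 134 ± 8.14 and 272 ± 5.51 CPM and Krtdap, a keratinocyte differentiation gene, at 113 ± 4.76 and 559 ± 394 CPM.

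The clone test covered 13224 genes, and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0, with a lowest adjusted p of 0.15. At an unadjusted p under 0.05 it had 1357 higher and 1087 lower, 18.5% of the genes, while DESeq2 called 622 higher and 352 lower and limma-voom called 0. Left with a lone TPA clone, the test called 3659 higher and 3889 lower without TPA clone 1 and 3282 and 3611 without TPA clone 2, each lone clone being assumed to vary like the TP clones. The TPA clones differed in their trend on GC, with a rho of -0.474 in clone 1 and 0.266 in clone 2 against 0.152 and 0.101 in the TP clones. With each library's trends on gene length and GC removed, chosen after the data were seen, 0 genes and 6 lists were called. The mucin list was positive in 6 of 7 tested members, the same direction as in bulk, with a median of 1.32, but did not pass (adjusted p = 0.16). Its mean level lay near the floor, at -0.598 and -0.676 log2 CPM in the TP clones and -0.081 and 0.456 in the TPA clones. Muc1 had 6 and 13 counts in the TP clones and 4 and 30 in the TPA clones, and its log2 fold change was -1.42 without TPA clone 2. The shared direction thus rests largely on low counts. Muc4 had an adjusted p of 0.0122 by DESeq2. Muc6 stood at 0.301 ± 0.368 and 0.775 ± 0.139 CPM (SD, n = 2), and summed counts were 3 and 8 for Muc13 and 0 and 4 for Capn9. Pten averaged 180 ± 6.34 and 134 ± 18.7 CPM (adjusted p = 0.28), and Trp53 and Brd9 had log2 fold changes of 0.44 and -0.04. Interferon response, higher in 26 of 26 members in bulk, was lower in 16 of 26 members in TPA clones (median -0.24) and did not pass (camera adjusted p = 0.106). The other lists that did not pass were gastric transcription factors, mucins and immediate early genes (each 0.16), and tuft, cell cycle and MYC (each 0.179). Further such lists were p53 (0.297), chief (0.299), mesenchymal (0.319), neck and intestinal (each 0.415), secretory granule exocytosis (0.538), and ER stress and parietal (each 0.918). Pit markers, with 2 members tested, and endocrine markers, with 1, were too few for a list test. Over all genes tested 0 members of any list were called. Adjusted over the list alone, p53 targets had 4 higher and 2 lower, gastric transcription factors 3 lower, mesenchymal genes 2 higher, and MYC and endocrine genes 1 higher each, and the lists given no such count had 0.

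Whether the guide's effect differs between clones and populations was tested on the difference of the fold changes. Over 14107 genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0, with a lowest adjusted p of 0.139. At an unadjusted p under 0.05 there were 1420 genes (10.1%), and DESeq2 had 182 higher and 185 lower. On simulated data at this spread edgeR's test recovered 0% of 2-fold and 0% of 4-fold differences, so its 0 calls could not show equal effects. Without bulk TP column 1 it called 15 higher and 16 lower. The genes called in each guide comparison shared 0 by edgeR, because each had 0 calls. By DESeq2, 50 genes were higher in both against 12.9 for independent lists, and 7 were lower in both against 2.18, but 15 were lower in bulk and higher in clones against 3.63. Fisher's exact test, two-sided, gave adjusted p of 9.55e-16, 0.0121 and 6.22e-06 for these overlaps. It counts genes as independent, which they are not, so these p are likely too low. At an unadjusted p under 0.05, chosen after the data were seen, 106 genes were higher in both against 60 expected, 59 were lower in bulk and higher in clones against 30.1, and 36 were lower in both against 26.2 (adjusted p = 0.0651). Fetub, a fetuin family protease inhibitor, was positive in both (log2 fold change 2.44 in bulk), while Dsg3 was -1.67 in bulk and 1.02 in clones, and Pigr, the receptor that carries IgA across epithelia, was 4.13 and -3.28. Across 12579 genes the fold changes had a Pearson r of 0.119 and a Spearman rho of 0.113, with 54% of the same sign, and genes are not independent replicates. That r was -0.0135 without TPA clone 2.

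The treatment comparison asks what dBRD9 does in TPA organoids, and here many genes passed the test. BRD9 protein is not measured in these data, so its loss is assumed and cannot be told apart from other effects of the compound. The largest fall among the named genes was that of Hp, haptoglobin (chromosome 8, 109575128 to 109579172, minus strand), from 50.3 ± 2.66 CPM with DMSO to 7.01 ± 1.49 CPM with dBRD9 (SD, n = 3), a log2 fold change of -2.84 ± 0.13 (SE). Tff2, the trefoil factor of mucous neck cells (chromosome 17, 31141049 to 31144282, minus strand), fell from 16.6 ± 2 to 4.33 ± 0.927 CPM. Spink5, an epithelial protease inhibitor (chromosome 18, 43963235 to 44022501, plus strand), fell from 183 ± 11.4 to 49.5 ± 3.34 CPM. Abca1, the cholesterol exporter (chromosome 4, 53030787 to 53159895, minus strand), rose from 20.4 ± 2.99 to 62 ± 6.51 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p were 1.27e-08 for Hp and Spink5, 6.23e-06 for Tff2 and 1.93e-06 for Abca1.

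Brd9 RNA (chromosome 13, 73937811 to 73960895, plus strand), the degrader's target as a protein, stood at 31.5 ± 2.75 CPM with DMSO and 27.6 ± 2.54 CPM with dBRD9 (SD, n = 3), with an adjusted p of 0.201, and of 0.0335 once trends on gene length and GC were removed. Arid1a stood at 108 ± 28.8 and 127 ± 18.6 CPM (adjusted p = 0.258, and 0.0103 without DMSO replicate 3), and Pten and Trp53 had log2 fold changes of 0.16 and -0.27 (adjusted p of 0.194 and 0.0574). Pten was 0.28 (adjusted p = 0.0328) with total counts only and -0.13 (adjusted p = 0.181) with the trends removed. Trp53 had an adjusted p of 0.0457 by DESeq2, 0.0275 with no low-count filter, 0.0459 with the trends removed, 0.0438 without dBRD9 replicate 2 and 0.0287 without DMSO replicate 2. Among the mucins, Muc1 fell from 23 ± 3 to 13.7 ± 1.69 CPM, a log2 fold change of -0.75 ± 0.13 SE (adjusted p = 0.00154). Muc5b, a gel-forming mucin, rose by 0.50 on the log2 scale (adjusted p = 0.0138), but its adjusted p was 0.0632 without dBRD9 replicate 1 and 0.0634 without DMSO replicate 2. Muc5ac stood at 3.11 ± 0.714 and 3.29 ± 0.391 CPM, and Muc4 at 12.8 ± 4.49 and 22.6 ± 12.7 CPM with an adjusted p of 0.0563. For Muc4 it was 0.0268 without DMSO replicate 3, 0.00353 without dBRD9 replicate 2 and 0.0333 with total counts only. It was 2.15e-09 with no low-count filter and 0.00165 with replicate numbers as a block. The mucin list did not pass (adjusted p = 0.726), with 1 of 6 members higher and 1 lower over all genes tested, and 2 higher and 3 lower adjusted over the list alone. Muc6, Muc13, Tff1 and Capn9 had summed counts of 17, 1, 3 and 0 with DMSO and 2, 0, 0 and 0 with dBRD9 and were not tested.

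Xenobiotic and glutathione genes were lower with dBRD9, with 11 of 18 members lower and 1 higher over all genes tested, and 13 lower and 2 higher adjusted over the list alone (median -0.43, camera adjusted p = 1.08e-08, and adjusted p = 0.112 with an estimated correlation). Gsta3 fell from 23.1 ± 3.13 to 6.92 ± 1.07 CPM, Gsta1 from 58.7 ± 9.74 to 23.2 ± 3.89 CPM, and Gstm1 from 162 ± 18 to 83.5 ± 8.7 CPM (SD, n = 3), all of them glutathione S-transferases. Cyp1b1 rose from 5.88 ± 1.46 to 18.3 ± 14.2 CPM. Neck and gland mucous cell markers were lower in 3 of 4 members over all genes tested, and 3 were lower and 1 higher adjusted over the list alone (median -0.82, adjusted p = 2.14e-05, and adjusted p = 0.112 with an estimated correlation). Besides Tff2, the water channel Aqp5 fell from 84 ± 10.2 to 37.6 ± 2.44 CPM, and Wfdc2, a secreted whey acidic protein, had a log2 fold change of -0.49, which was -0.18 (adjusted p = 0.166) once trends on gene length and GC were removed. Of the pit markers, Psca fell from 376 ± 59.4 to 170 ± 18.1 CPM, 1 of 3 members called over all genes and adjusted over the list alone, and the list did not pass (adjusted p = 0.0741).

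Squamous forestomach markers were lower with dBRD9 in 7 of 15 members and higher in 2 over all genes tested, and 8 and 2 adjusted over the list alone (median -0.35, adjusted p = 7.25e-04, and adjusted p = 0.312 with an estimated correlation). Krt4, a keratin of mucosal squamous epithelium, fell from 65.6 ± 6.47 to 30.2 ± 3.59 CPM (SD, n = 3), and Sprr1a, a cornified envelope protein, from 185 ± 19.9 to 118 ± 4.99 CPM. Dsg3 and Trp63 rose by 0.51 and 0.33 on the log2 scale. The squamous list did not pass once trends on gene length and GC were removed (adjusted p = 0.216). Hypoxia and glycolysis was lower in 6 of 14 members, and in 8 adjusted over the list alone (median -0.22, adjusted p = 0.00382, and adjusted p = 0.177 with an estimated correlation). Ldha, lactate dehydrogenase A, fell from 4468 ± 232 to 3446 ± 125 CPM, and Ndrg1, a hypoxia-induced gene, from 849 ± 29.5 to 606 ± 5.88 CPM. Cholesterol synthesis was lower in 5 of 18 members over all genes tested, and 6 were lower and 1 higher adjusted over the list alone (median -0.17, adjusted p = 0.0497, and adjusted p = 0.703 with an estimated correlation). Once trends on gene length and GC were removed, 10 were lower and 1 higher. Fdps fell from 463 ± 39.1 to 331 ± 27.5 CPM, while the list's adjusted p was 0.122, 0.0698 and 0.155 without dBRD9 replicate 2, dBRD9 replicate 3 and DMSO replicate 2, and 0.0707 with replicate numbers as a block.

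Lists that did not pass held genes that did. The O-glycosylation list (adjusted p = 0.501) had 3 of 22 members higher and 5 lower, and 4 and 5 adjusted over the list alone. Fut2, the fucosyltransferase of the secretor antigen, fell from 5.85 ± 1.14 to 1.76 ± 0.155 CPM (SD, n = 3), and C1galt1, which makes the core 1 glycan, rose from 29.9 ± 1.88 to 45.4 ± 6.39 CPM. SWI/SNF subunits (adjusted p = 0.199) had 5 of 26 members higher and 1 lower, and 6 and 1 adjusted over the list alone, but 3 higher and 6 lower of 24 once trends on gene length and GC were removed. The PBAF subunits Pbrm1 and Arid2 rose by 0.53 each on the log2 scale, and by 0.30 and 0.26 with the trends removed. Of the stromal and immune list (adjusted p = 0.0538), 2 of 4 tested members fell in each adjustment, Cd14 from 133 ± 6.44 to 70.1 ± 7.89 CPM and Cd68 by a log2 fold change of -0.52, which was -0.22 (adjusted p = 0.0997) once trends on gene length and GC were removed. Gastric transcription factors (adjusted p = 0.0902) had 4 of 14 members lower, among them Elf3, an epithelial ETS factor that fell from 350 ± 21.9 to 238 ± 18.9 CPM, and Spdef, an ETS factor of secretory cells, at 2.12 ± 0.17 and 0.92 ± 0.511 CPM. Cell cycle (adjusted p = 0.137) had 6 of 28 lower and ER stress (adjusted p = 0.422) 3 higher and 4 lower of 19, with the unfolded protein sensor Ern1 rising from 11.3 ± 3.1 to 23.9 ± 2.37 CPM. The remaining lists were MYC (adjusted p = 0.0978), intestinal (0.137), tuft (0.422), interferon (0.454), mesenchymal (0.501), WNT (0.932), p53, secretory granule exocytosis and parietal (each 0.98), and NF-kB and immediate early genes (each 0.983). Chief and endocrine markers had 2 and 0 members tested. Over all genes tested, MYC had 3 of 14 members lower, intestinal 2 of 5 lower and tuft 1 of 3 lower. Interferon had 1 higher and 3 lower of 26, mesenchymal 1 and 1 of 11, WNT 2 and 3 of 10, p53 2 and 3 of 15, secretory granule exocytosis 1 and 2 of 21, NF-kB 1 and 2 of 16, and immediate early genes 2 and 1 of 13. Adjusted over the list alone, p53 had 4 and 4 and NF-kB 2 and 2, and the counts of the others were equal to these, as were those of gastric transcription factors, cell cycle and ER stress. Median and mean differed in sign from the camera direction for WNT and NF-kB, and median from mean for immediate early genes.

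**Figure D2:**
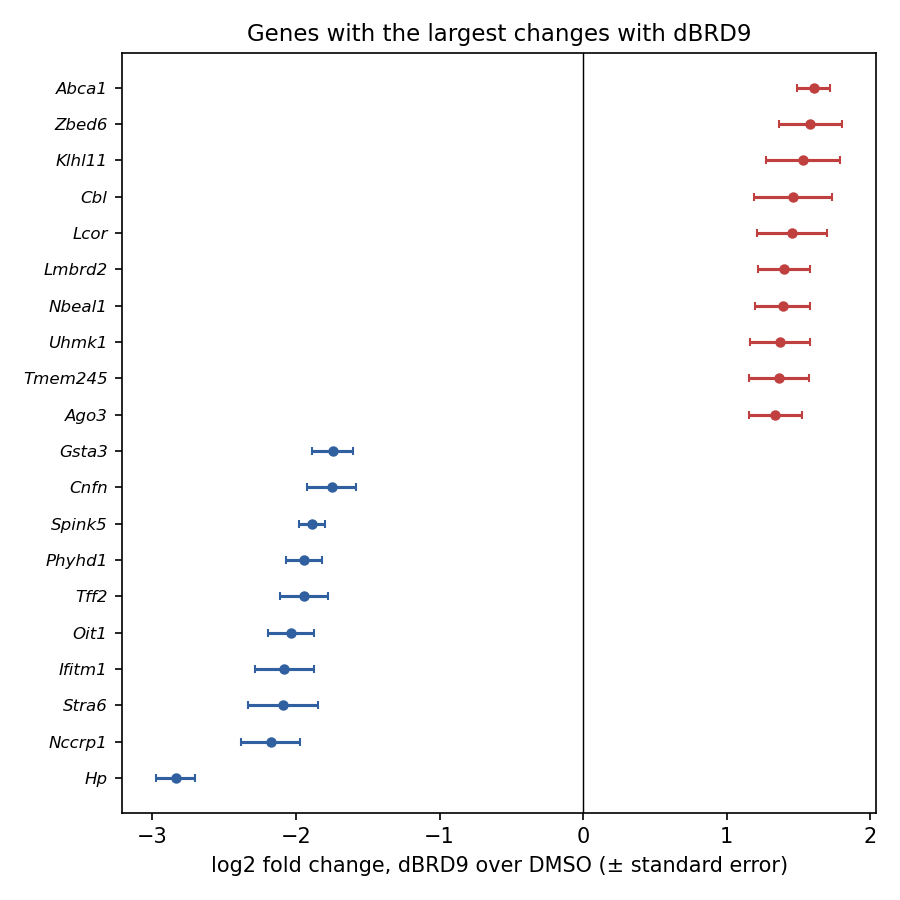
Log2 fold change, dBRD9 over DMSO, of the 10 genes with the largest rise (red) and the 10 with the largest fall (blue) by the naming rule, with the standard error as bars and 3 libraries per group. Hp had the lowest value, -2.84, and Abca1 the highest, 1.60.

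In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1484 genes higher and 1338 lower with dBRD9 among 12484 tested, 22.6% of them, at median log2 fold changes of 0.47 and -0.42. At a fold change of at least 2 there were 104 higher and 159 lower. The other named rises were Zbed6, Klhl11, Cbl, Lcor, Lmbrd2, Nbeal1, Uhmk1, Tmem245 and Ago3, at log2 fold changes of 1.58 down to 1.34. The other named falls were Nccrp1, Stra6, Ifitm1, Oit1, Phyhd1, Cnfn and Gsta3, from -2.18 to -1.74. Scaling by total counts alone moved the median of all genes by 0.116 and gave 2691 higher and 679 lower. The calls were 659 and 792 without dBRD9 replicate 1, 634 and 605 without dBRD9 replicate 3, and 767 and 781 without DMSO replicate 1. With all 6 groups in 1 fit they were 0 and 2. That fit shares 1 dispersion per gene over all groups. The common biological coefficient of variation was 0.487 in bulk and 0.313 in clones against 0.0915 here, so it tends to overstate the spread of the treatment libraries.

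Fold changes with dBRD9 followed gene length across 12012 annotated genes, with a Spearman rho of 0.494 on exonic length, and genes are not independent replicates. The median exonic length was 8224 bases in genes called higher, 2589 in genes called lower and 4408 in all. With each library's trends on length and GC removed, 954 genes were called higher and 1363 lower, of which 746 and 797 had been called in the same direction before. Hp (-2.58), Tff2 (-1.58), Spink5 (-1.94), Abca1 (1.36), Muc1 (-0.57), Gsta1 (-1.05) and Aqp5 (-1.06) stayed called at those log2 fold changes, and Muc5b (0.22, adjusted p = 0.0781) did not. The median went from -0.43 to -0.37 in the xenobiotic list, from -0.82 to -0.62 in the neck and gland list and from -0.17 to -0.21 in the cholesterol list. It went from -0.35 to -0.14 in the squamous list, a loss of over 50%, and from -0.22 to -0.14 in the hypoxia list.

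**Figure D3:**
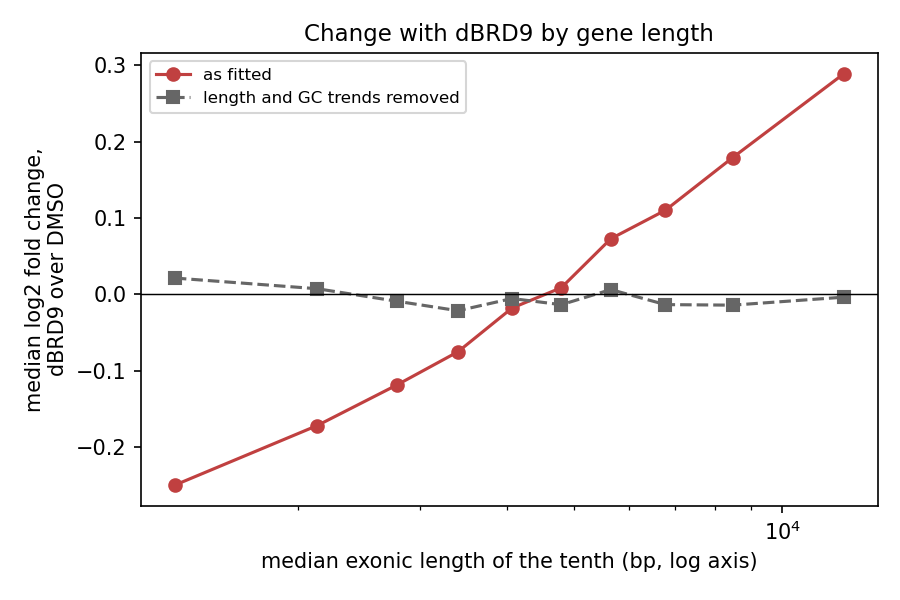
Median log2 fold change, dBRD9 over DMSO, in 10 equal groups of genes ordered by exonic length, against each group's median exonic length in bases. Red circles are as tested and run from -0.25 in the shortest genes to 0.289 in the longest, and grey squares, after each library's trends on length and GC were removed, run from -0.0216 to 0.0212.

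The last comparison asks whether genes that stand higher with the Arid1a guide fall with dBRD9. By DESeq2, 79 genes were higher in bulk TPA and lower with dBRD9 against 31.1 for independent lists, and 109 were higher in TPA clones and lower with dBRD9 against 56.4 (Fisher's exact test, two-sided, adjusted p = 1.04e-14 and 2.43e-11). Genes lower with the guide and higher with dBRD9 numbered 12 against 8.51 in bulk (adjusted p = 0.24) and 52 against 36.8 in clones (adjusted p = 0.0168). Another 69 were lower in clones and lower with dBRD9 against 33.6 (adjusted p = 1.43e-08), so in clones both directions of the guide shared genes with the falls. By edgeR's adjusted p every overlap was 0, since each guide comparison had 0 calls. At an unadjusted p under 0.05 in the guide comparisons, chosen after the data were seen, 129 genes were higher in bulk TPA and lower with dBRD9 against 66.4, and 190 were higher in TPA clones and lower with dBRD9 against 124. Genes lower with the guide and higher with dBRD9 then numbered 65 against 34.8 in bulk (adjusted p = 1.23e-06) and 171 against 124 in clones (adjusted p = 1.4e-05), and 160 were lower in clones and lower with dBRD9 against 110 (adjusted p = 1.35e-06). Once trends on gene length and GC were removed, genes higher with the guide and lower with dBRD9 were 86 against 49.2 in bulk and 206 against 135 in clones. The opposite overlaps were then 69 against 42.9 and 145 against 122. Fisher's exact test counts genes as independent, which they are not, so the p of these overlaps are likely too low. DESeq2 also had 58 of 104 calls false on simulated bulk data and 48 of 152 on simulated clone data. These shares depend on how many genes truly change, which the simulation fixed and which is unknown for the real data. They show that false calls occur at this spread, but not what share of the real calls is false.

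Gsta1 was 2.26 on the log2 scale in clones and -1.35 with dBRD9, Chit1, a chitinase of macrophages, was 3.15 and -0.83, and Ankrd37 was 2.26 and -0.43. Atf5, a stress-response transcription factor, was -1.61 in clones and -0.47 with dBRD9, and Bcat2, a mitochondrial aminotransferase of branched-chain amino acids, -1.47 and -0.55. Fetub was 2.44 in bulk and -0.69 with dBRD9, Dcxr, a reductase of dicarbonyls and xylulose, 2.25 and -0.86 (but -1.32 in clones), and Pcdh7, a protocadherin, was negative in bulk and 0.82 with dBRD9. Cyp1b1 went the same way in both, 6.33 in bulk and 1.61 with dBRD9. As a set, the 618 genes higher in bulk TPA at an unadjusted p under 0.05 were lower with dBRD9 (median -0.06, camera adjusted p = 0.047, and adjusted p = 0.503 with an estimated correlation). The sets of genes lower in bulk, higher in clones and lower in clones did not pass, with adjusted p of 0.0917, 0.114 and 0.866. With an estimated correlation the set higher in clones had a camera adjusted p of 0.308. Across genes the fold changes of bulk and dBRD9 had a Pearson r of -0.0553 and a Spearman rho of -0.0838 (12241 genes), and those of clones and dBRD9 -0.0637 and -0.0196 (12187 genes), and genes are not independent replicates. The bulk r was 0.00634 with DESeq2's fold changes and 0.00293 without TPA column 2.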

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

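The test of squamous share was chosen only after the result was seen, and so was the alternative that removes length and GC trends. The 1484 higher and 1338 lower calls with dBRD9 went with gene length, and 56.7% of the called genes with an annotation stayed called in the same direction once the trends were removed. That share lies between the bounds of 50% and 80% written beforehand. A length bias and an effect of dBRD9 on long genes thus cannot be told apart for the calls as a whole. The trend differed within groups too, with a rho on length of 0.525, 0.115 and 0.412 in the dBRD9 libraries and -0.505, -0.31 and -0.23 in the DMSO libraries. For the xenobiotic and glutathione list the correction argues against length as the whole cause, because its median moved from -0.43 only to -0.373. Lower expression of these genes through dBRD9 stays open as a hypothesis. The real split called 2822 genes and 1 of 10 splits of the 6 libraries reached that, the highest other being 0, but 10 splits are too few for a share under 0.05.

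The mucin list stood higher in bulk TPA by a median of 2.41. It averaged 4.67 and 1.14 log2 CPM in the TP columns and 4.79 and 5.98 in the TPA columns, so much of the gap came from TP column 2. The lowest median under the other scalings was 2.37. These scalings moved the median of all genes from -0.0292 only to -0.0553, too little to test scaling as a cause. A lower share of squamous-like cells in the TPA libraries would raise the markers of every other epithelial type only if those types kept their proportions. Of 7 other epithelial lists, 3 had a positive median. A rise of 1 type alone could give this too, so the count cannot decide. The squamous list averaged 7.11 and 6.83 log2 CPM in the TP libraries and 5.72 and 6.53 in the TPA libraries. Its member Krt5, a keratin, stood at 692 and 7370 CPM in TP and 1972 and 2618 CPM in TPA, and did not separate the groups. A change in cell composition could contribute and stays open. The stages named premalignant and tumor go with the Arid1a guide and cannot be told apart from it. The treatment libraries with DMSO, also TPA, did not hold these mucin levels. Muc1 stood there at 19.9 to 25.5 CPM, against 669 and 549 CPM in bulk TPA. Muc5ac stood at 2.24 to 3.6 CPM, against 64.2 and 326 CPM. Muc4 stood at 9.59 to 17.3 CPM, below both bulk TP columns (155 and 27.3 CPM). The high levels are thus not shared by all TPA libraries, and the cause was not tested. In the clones the mucin list had a median of 1.32 with 6 of 7 members positive but did not pass (camera adjusted p = 0.16). It lay near the floor there, at -0.598 and -0.676 log2 CPM in the TP clones and -0.081 and 0.456 in the TPA clones. The difference between clone and bulk effects passed for no gene by edgeR, which recovered 0% of simulated 4-fold differences and so could not decide. It had 1420 genes at an unadjusted p under 0.05, and DESeq2 had 182 higher and 185 lower.

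In bulk TPA column 2, genes of chromosome 12 lay below the other libraries, with a median shift of -0.358 over 447 genes. Length and GC bias is argued against, as the median less that of the other chromosomes went from -0.368 only to -0.349 with the correction (-0.47 in itself, because the correction also moved the other chromosomes of that library to -0.12), and so is chance placement of genes, whose largest median had a 95th percentile of 0.0882 over 1000 shuffles. That value does not set chromosome 12 apart, since 44 of 80 pairs of chromosome and bulk library lay past it, among them chromosome 13 in TP column 2 (-0.313), chromosome 8 in TP column 1 (0.29) and chromosome 2 in TPA column 2 (0.287). A few local clusters of genes stay open, since 3 of 4 consecutive blocks of the chromosome's genes had a median over 50% of the whole, and the blocks ran from -0.554 to -0.0268. The shift was 0.204 and 0.112 in the TP columns and 0.0072 in TPA column 1, and no biological explanation was tested.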

How the results depend on the processing

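The alternatives with an unadjusted p, with length and GC trends removed and with a block on bulk column number were chosen only after the data were seen, and all others beforehand. Where a group kept a lone library, it was assumed to vary like the other group. The cause of each change below was not tested, except that a fold minimum can only shorten a list of calls. By design the fit of all 6 groups shares 1 dispersion per gene, which tends to understate the spread in bulk and overstate it in the treatment libraries. Bulk calls, 0 by edgeR, were 357 higher and 87 lower by DESeq2 and 671 and 359 with all 6 groups in 1 fit. A replicate block on bulk column number gave 0 and 0 calls and 9 lists. Same-number columns had a correlation of -0.207 once group means were taken out, and columns of unlike number 0.207, a pairing for which no block was fitted. Clone calls, also 0, were 622 and 352 by DESeq2, 22 and 4 without a low-count filter, 355 and 286 with 6 groups, 68 and 10 with a replicate block (Gsta1 and Ankrd37 among them, at an adjusted p of 0.021 and 0.03), and 0 to 3659 higher and 0 to 3889 lower with a library left out, the TPA clones giving the high values. The dBRD9 calls of 1484 and 1338 were 2691 and 679 with total counts only, 0 and 2 with 6 groups, 954 higher with trends removed, 104 and 159 at a fold of at least 2, and 634 to 1633 and 605 to 1550 with a library left out. The replicate block gave 1322 and 1148, of which 1255 and 1095 were shared, and called Muc4 as well (adjusted p = 0.00165). The difference between clone and bulk effects, 0 and 0, was 182 and 185 by DESeq2 and 0 to 15 and 0 to 16 with a library left out, 15 and 16 without bulk TP column 1.

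Camera called 8, 8 and 5 lists in bulk, clones and dBRD9. With an estimated correlation 0, 0 and 0 lists were called. Among the lists called in bulk that estimate was 0.933 for interferon, 0.818 for pit and 0.679 for xenobiotic genes. It was lowest for mesenchymal genes (0.212) and squamous markers (-0.0128), the latter alone lying below the preset 0.01. Where the estimate lies far above the preset, the preset p are likely too low. Over all lists tested fry called 0, 0 and 6, and its mixed form 1, 13 and 21. The 6 held 4 of camera's 5 with dBRD9, without cholesterol synthesis (adjusted p = 0.062). With a library left out, 3 to 11, 8 to 11 and 4 to 10 were called. The mesenchymal list in bulk ran from an adjusted p of 6.27e-13 to 0.952, where it reversed. Overlaps, 0 by edgeR, were 50 higher and 7 lower in both guide comparisons by DESeq2 and 106 and 36 at an unadjusted p. Genes higher in bulk and lower with dBRD9 were 79 by DESeq2, 129 at an unadjusted p and 86 with trends removed as well, and the opposite 12, 65 and 69. For clones these were 109, 190 and 206, and the opposite 52, 171 and 145, with ranges of 0 to 447 and 0 to 692 when a library was left out. Against independent lists, these were 447 and 692 against 342 and 445 without TPA clone 1, but 356 and 420 against 324 and 422 without TPA clone 2, where the opposite overlap had an odds ratio of 0.991 (Fisher's exact test, two-sided, p = 0.902). The correlation of bulk and clone fold changes ran from -0.0135 to 0.163, and that of bulk and dBRD9 from -0.0909 to 0.00293, with 0.00634 by DESeq2. That of clones and dBRD9, -0.0637, ran from -0.0838 to -0.00411, the latter without TPA clone 2.

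Of the named genes followed under every alternative, 414 values in bulk, 384 in clones and 910 with dBRD9 kept their direction and their side of the threshold. Another 46, 127 and 13 passed it under an alternative only, and 62 with dBRD9 lost their call, 56 of them with 6 groups in 1 fit, while 15, 3 and 3 values of genes that were called in neither case changed sign. List tests kept their side in 39, 38 and 44 cases and lost the call in 32, 26 and 11. Depth limits low genes, as 0 counts allow 0.11 to 0.233 CPM, and the spread between bulk libraries left edgeR with 0% of simulated 4-fold changes.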

Other observations

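The levels in this part were chosen for a closer look only after their values were seen, and no further test was run on the single genes. Keratin 8 (Krt8), the simple epithelial keratin that pairs with keratin 18, stood at 0.513 CPM in TPA clone 1 and at 68.6 to 195 CPM in the other 3 clones, while Krt18 stood at 389 to 697 CPM in all 4. Krt5, the basal keratin of squamous epithelium, stood at 692 and 7370 CPM in the bulk TP columns and 1972 and 2618 CPM in the bulk TPA columns. Stromal and immune transcripts were highest in bulk TPA column 2, with the collagen Col1a1 at 10.8 CPM against at most 0.466 CPM in the other 3 bulk libraries and the leukocyte antigen Ptprc at 9.47 CPM against at most 1.01 CPM.

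The Y-linked translation factor Eif2s3y stood at 0.933 and 14.1 CPM in the bulk TP columns and 0.243 and 163 CPM in the bulk TPA columns. It stood at 58.4 to 106 CPM in the clones and at 0 in all 6 treatment libraries, where Ddx3y, another Y-linked gene, stood at 80.2 to 111 CPM. In bulk, Ddx3y stood at 125 and 22 CPM in the TP columns and 88.1 and 124 CPM in the TPA columns. A Y-linked transcript was thus present in every bulk library. Eml1, a microtubule-binding protein gene of chromosome 12, stood at 1.17 and 18.2 CPM in the bulk TP columns. In the bulk TPA columns it stood at 1.58 and 28.1 CPM. Eml1 and Eif2s3y were thus both higher in column 2 of each group. Across all genes same-number columns had no such likeness, with a correlation of -0.207 once group means were taken out. Columns of unlike number stood at 0.207, the mirror value that 2 columns per group force. In the clones Eml1 stood at 15.8 to 24.4 CPM, and in the treatment libraries at 0.659 to 1.71 CPM. In TPA clone 2 the genes of chromosome 7 had a median shift of -0.22 over 1008 genes, past the 95th percentile of 0.0837 over shuffled positions, as were 13 of 80 pairs of chromosome and clone library. It was -0.298 with length and GC trends removed, and the 4 consecutive blocks of its genes ran from -0.241 to -0.175. The shift was 0.121 in TPA clone 1 and 0.0795 and 0.0672 in the TP clones.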
